A study of Drosophila melanogaster with 2 samples.

How the data were processed

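Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in 2 libraries of whole Drosophila melanogaster embryos of both sexes, aged 0 to 24 h. The flies carried a transgene for CG18476, the protein of a gene on 3R, fused at its carboxyl end to eGFP, a green fluorescent protein, and the precipitation used an antibody against GFP. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the libraries are biological replicates 1 and 2 of 1 group. A mock precipitation or an untagged strain was not analysed here.

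Peaks were called by the authors per sample and also on the pooled reads of both samples, each against a control, per the README texts deposited with the files. For each of 2 genome builds, dm3 and dm6, the deposited lists are a list of peaks and background regions for each replicate, a list of the same kind for the pooled reads, and an irreproducible discovery rate (IDR) thresholded set derived from those lists. The thresholded set, labelled optimal, was therefore selected for reproducibility by IDR, from lists that include those of the replicates. Its match rates in the replicates are for that reason not independent evidence. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own deposited value in the authors' units. In the peaks compared here the pooled signal was close to the sum of the replicates' signals, with a median ratio of 1.00, so the deposited signal was not scaled to a common depth. The deposited -log10 q value of each peak, also the authors', reached 3.71 at most in the dm6 pooled list and was used only to describe the lists. Read counts and sequencing depth are unknown from these lists, so no value below carries an error from read counting. The dm6 lists of the pooled reads and of each replicate hold exactly 30000 regions each.

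All positions are in dm6, 1-based. The dm6 peaks lay within the chromosome lengths of the reference assembly. Genes and transcription start sites (TSSs) came from Ensembl release 115 for the arms 2L, 2R, 3L, 3R, 4 and X, without transposable element entries, and the sequence from the matching RefSeq assembly. The dm3 lists were compared with dm6 by counts only, and no coordinates were converted. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.

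A thresholded peak was matched to a replicate when one of the 3995 highest-signal regions of that replicate overlapped it by at least 0.5 of both lengths, and the overlap expected by chance came from 1000 random placements of replicate 1's regions. A promoter peak had its summit within 500 bp of a TSS. Promoter shares were set against 1000 random placements of the summits on the same chromosomes (one-sided). Genes with a promoter peak were counted inside and outside 27 gene lists, and on X against the large autosome arms, with Fisher's exact test, two-sided. The background was all 13945 protein-coding genes on the 6 arms, or all 18164 genes for lists of RNA genes. Sites of 20 known motifs in the 101 bp at each summit were compared with a window 1000 bp to one side, drawn at random, by the exact McNemar test, and at promoter summits with the same offsets at promoters without any listed region by Fisher's exact test. Every 8-mer, strands merged, was tested in the same paired windows on 2L and 2R, and those past the threshold again on 3L, 3R, 4 and X. Benjamini-Hochberg adjustment was applied over the lists, over the motifs and over the 8-mers, with a threshold of 0.05. Median signals were compared by a permutation test with 100000 resamples, two-sided. Intervals of shares are exact binomial (Clopper-Pearson) at 95%, and intervals of odds ratios are exact at 95%. They cover the counting of peaks or genes, not differences between embryos. With 1 group of 2 libraries, no test between groups was possible.

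The gene lists, motifs, tests and most alternatives were fixed before the data were examined. Genes were named by a rule fixed then as well: the gene nearest to each of the 25 thresholded peaks of highest signal, CG18476 itself, the 4 members with the highest promoter signal of each list past the threshold, and up to 2 members of each other list, with neighbours that share the summit. Not every gene under the rule is named here. Of the list symbols, Z4 and calypso matched no gene under those names, and 5 others were matched through synonyms. The alternatives were the upper part of the peaks by signal, each replicate's own list, other promoter distances, peak midpoints, other windows, flanks, backgrounds and tests.

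The procedures were tested on 4000 simulated peaks. Random peaks gave a promoter fold of 0.987, 0 lists, 0 motifs and 0 8-mers past the threshold. These peaks lay at uniformly drawn positions, without the low G+C content of the real summits. The simulation therefore could not show whether motif and 8-mer calls arise from base composition. With planted promoter peaks the fold was 3.60, a planted list ranked 1 by its p, and an 8-mer planted in 3% of windows was the only 1 kept. A set sharing every other peak was matched at 50.5%.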

Results

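The data map the chromatin recovered with CG18476-eGFP from whole Drosophila embryos of 0 to 24 h in 1 group of 2 biological replicates. The authors' thresholded dm6 set held 3995 peaks, with signal values from 60.6 to 1948 and a median of 98.2. The most frequent peak width was 430 bp, shared by 79.0% of the peaks. Sequencing depth is unknown from the lists, and a peak's signal is the authors' value for the pooled reads. For the strongest peaks the signals in replicate 1 and in replicate 2 are given in that order as the measure of spread.

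The comparison of the replicates asked how far the same sites were recovered from separate embryo collections. All 25 of the strongest thresholded peaks, among them those at ptc, Ugalt, Pgant5 and Chro, ranked 27 or better among the 30000 regions of each replicate, which their choice by pooled signal in part fixes. Ranked by each replicate's own signal, 69.4% of the 500 strongest regions of replicate 1 were among the 500 strongest of replicate 2. Of the 3995 thresholded peaks, 74.6% (95% interval 73.2 to 75.9) were matched in replicate 1, 80.4% (79.1 to 81.6) in replicate 2 and 63.8% (62.2 to 65.2) in both. Random placement gave a mean overlap of 1.04% and at most 1.58%. These shares are not independent evidence of agreement, since the thresholded set was chosen for reproducibility. Between the replicates' own lists, before any threshold, 70.8% (69.4 to 72.2) of the 3995 strongest regions of replicate 1 were among the 3995 strongest of replicate 2, and 45.7% of all 30000 were matched. In the 3513 thresholded peaks present in both full lists, Spearman's rho of the signal was 0.612 across peaks, which are not independent replicates. The ratio of replicate 2 to replicate 1 had a median of 1.23 and an interquartile range from 0.980 to 1.55. The match shares moved with the overlap required, up to 86.2% in replicate 1 and 89.4% in replicate 2 for an overlap of at least 1 bp.

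**Figure D1:**
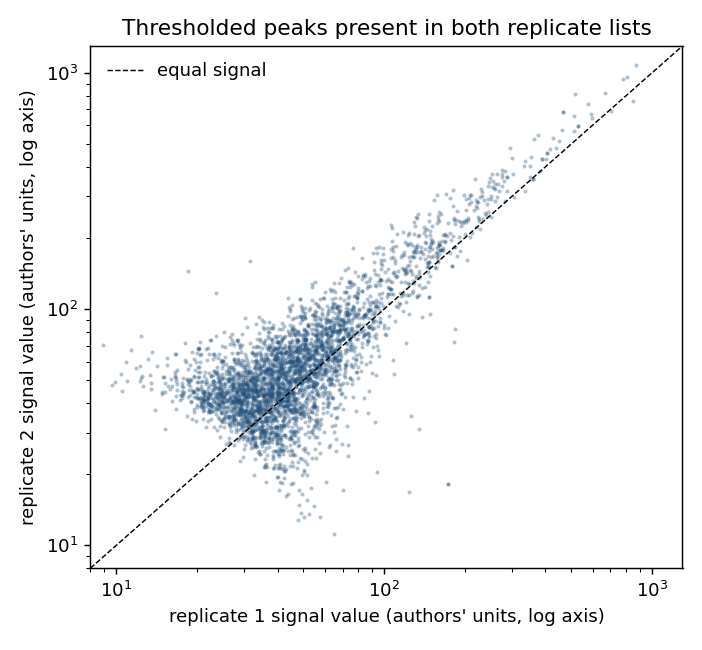
Signal value of replicate 1 (x axis) against replicate 2 (y axis), authors' units on log axes, for the 3513 thresholded peaks found in both replicate lists; each point is a peak and the dashed line marks equal signal. The strongest peaks lie close together along the diagonal, and the spread widens at low signal, with a Spearman's rho of 0.612 over all points.

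The strongest peaks show which loci carried the highest signal. The highest lay at 3L:7323247-7323754, near the TSSs of RhoGEF4, which encodes a guanine nucleotide exchange factor, and Rint1, with the summit 65 bp from the RhoGEF4 TSS and a signal of 1948 (875 in replicate 1 and 1078 in replicate 2). The peak at ptc, which encodes the Hedgehog receptor Patched, had its summit 263 bp from the TSS (2R:8649120-8649599) and a signal of 1727 (780 and 946). Of the 25 strongest, 17 were promoter peaks. Genes of sugar transport and glycosylation stood among these: Pgant5, a GalNAc transferase gene (2L:5092930-5093447, signal 1489, 666 and 822), Ugalt, a UDP-galactose transporter gene (X:2703676-2704099, signal 1328, 514 and 815), and nac, a GDP-fucose transporter gene (3R:8303894-8304346, signal 1075, 511 and 565). No list for that theme was fixed, and its enrichment was not tested.

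Further promoter peaks among the 25 lay at CG33229 and lncRNA:CR42862 (signal 1405), CG14100 (1164), wech (1129), px (1035), Bulli and CG10147 (969), Rtnl1, a reticulon gene (952), Chro and Ssl1 (922), and tRNA:Thr-TGT-2-3 (918). PNPase, which encodes polynucleotide phosphorylase, had a signal of 891, ThrRS, which encodes threonyl-tRNA synthetase, with its neighbour Patsas had 845, lncRNA:CR44619 had 841, and CG9147 with Fbw5 had 798. The other 8 strong peaks lay away from promoters. A peak at 3R:6908023-6908560 with a signal of 1750 (804 and 957) lay in a 3' UTR where Antp, a Hox gene, and CG46458 overlap, 3617 bp from the nearest TSS, that of lncRNA:CR43252. An intergenic peak at 3L:18272168-18272792 (signal 1604, 852 and 762) lay 20380 bp from the nearest TSS, that of CheA75a. The introns of CG11050 (signal 1305), jumu, a forkhead factor gene (1254), spin (1249, nearest TSS Got1) and ush (1164, nearest TSS cbt) held 1 each, and intergenic peaks lay 1303 bp from DNAlig3 (898) and 2065 bp from rols (819).

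The gene of the tagged protein itself carried a peak. CG18476 lies at 3R:11674920-11678116 on the minus strand, and the peak at 3R:11678140-11678422 had its summit 150 bp upstream of the TSS and a signal of 319 (133 in replicate 1 and 187 in replicate 2), rank 210 of all thresholded peaks. Within 20 kb of the gene lay 8 thresholded peaks, against a median of 2 over protein-coding genes. The strongest of them, with a signal of 717 (358 and 356), was at 3R:11669067-11669431 in a coding exon of CG42327, 8895 bp from the CG18476 TSS. A second summit was called in the same region, with a signal of 113. These neighbouring peaks were singled out after their values were seen.

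**Figure D2:**
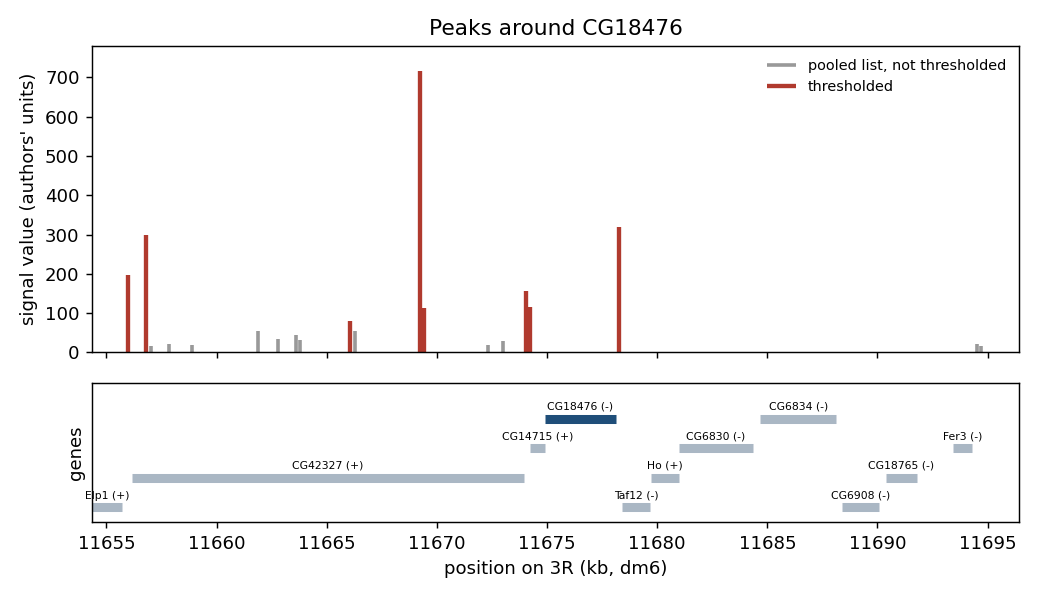
Signal value (y axis, authors' units) of thresholded peaks (red) and of other regions of the pooled list (grey) by summit position on 3R in kb of dm6 (x axis), over protein-coding genes drawn as bars with their strand, around CG18476 (dark blue). The peak upstream of CG18476 has a signal of 319, and the highest peak, in CG42327, has 717.

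The position of the peaks relative to genes asked where in the genome the protein was recovered. Promoters held 2022 of the 3995 summits, 50.6% (95% interval 49.1 to 52.2), 3.73-fold the 13.6% ± 0.525 (SD, 1000 random placements) of random positions. Coding exons held 15 summits, 0.375% against 13.7% of random positions, and 3' UTRs held 31, 0.776% against 4.40%. Introns held 34.4% against 39.4%, and intergenic sequence 12.3% against 27.3%. The promoter share exceeded every placement, with a one-sided p of 0.001, the smallest that 1000 placements can give. The differences for coding exons, 3' UTRs, introns and intergenic sequence had a two-sided permutation p of 0.002, also the smallest possible. The median distance from a summit to the nearest TSS was 482 bp, and 13.8% of summits lay more than 5 kb away. Regions of the pooled list that did not enter the thresholded set were promoter regions in 25.7% of 26004 cases (odds ratio 2.96, 2.77 to 3.17, Fisher's exact p = 6.72e-211).

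**Figure D3:**
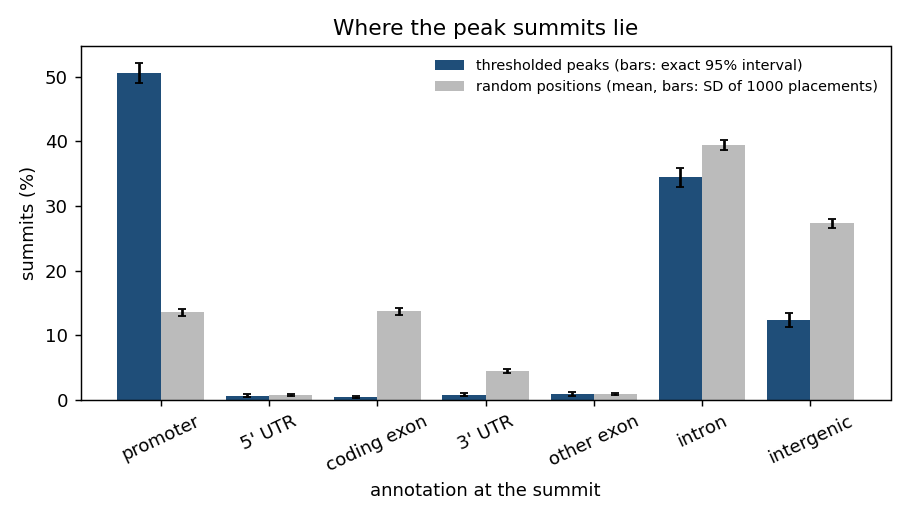
Share of the 3995 thresholded summits (dark bars, error bars exact 95% intervals) and of random positions (grey bars, mean and SD of 1000 placements) in each annotation class on the x axis, in percent on the y axis. Promoters hold 50.6% of summits against 13.5% of random positions in the set of placements drawn for this plot, and coding exons 0.375% against 13.7%.

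Promoter peaks were also the stronger ones. Their median signal was 104 (interquartile range 76.9 to 165, 2022 peaks), against 92.9 (72.4 to 132, 1973 peaks) for distal peaks, a difference of 11.5. The permutation p was 1e-05, the smallest that 100000 resamples can give. Among the strongest 998 peaks, 60.3% were promoter peaks, and among the weakest 999, 43.6% were. The ranges of signal overlapped widely, and the ptc peak and the peak within Antp, one promoter and the other not, differed little.

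The gene lists asked which kinds of genes had a promoter peak. Of 13945 protein-coding genes, 2468 (17.7%) had one. Cytoplasmic ribosomal protein genes had one in 50 of 82 cases (61.0%, odds ratio 7.39, 4.64 to 11.9, adjusted p = 6.66e-17, Fisher's exact test), with the highest signals at RpL32 (303), RpS27 (270.5) and RpL7 (259). Of the abundant housekeeping genes, 14 of 24 had one (58.3%, odds ratio 6.541, 2.70 to 16.5, adjusted p = 4.23e-05, Fisher's exact test), led by the glycolytic genes Gapdh2 (582) and Eno (299.6) and by Hsp83 (179) and RpLP0 (114). Mitochondrial ribosomal protein genes had one in 28 of 73 cases (38.4%, odds ratio 2.91, 1.75 to 4.79, adjusted p = 0.000116, Fisher's exact test), led by mRpL41 (768), mRpS10 (757), mRpS23 (656) and mRpL23 (638). The median signal over bound members was 106 for the mitochondrial and 108 for the cytoplasmic ribosomal list.

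Genes for proteins that organise chromatin also had more promoter peaks. Of 14 insulator and architectural protein genes, 8 had one (57.1%, odds ratio 6.22, 1.89 to 21.8, adjusted p = 0.00311, Fisher's exact test): Chro, which encodes Chromator, had a signal of 922, Cp190 had 439, Ibf2 had 199 and Trl, which encodes GAGA factor, had 193. Of 23 Polycomb and trithorax group genes, 9 had one (39.1%, odds ratio 2.996, 1.14 to 7.44, adjusted p = 0.0342, Fisher's exact test), led by ph-p (744), brm (344), E(z) (187) and Su(z)12 (163). That call was lost when the labels were shifted along the gene order, with an adjusted permutation p of 0.0707, and also in either replicate's own list, in the upper 1997 peaks and at promoter distances of 250 and 1000 bp, with odds ratios from 2.34 to 3.11 in those settings. Against genes with any region of the pooled list as background, the odds ratios of the ribosomal protein (3.31, adjusted p = 3.37e-06) and abundant housekeeping (3.67, adjusted p = 0.0243) lists were lower but stayed past the threshold, as they did in the upper 1997 peaks (4.63 and 3.64), and the insulator (3.67, adjusted p = 0.120), mitochondrial ribosomal (1.51, adjusted p = 0.287) and Polycomb (1.65, adjusted p = 0.603) lists did not pass (Fisher's exact test). The insulator list, with 12 genes in that background, had an odds ratio as high as that of the abundant housekeeping list.

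Other groups had fewer promoter peaks than the rest. None of the 179 chemoreceptor genes (0%, 95% interval up to 2.04, adjusted p = 1.47e-14, Fisher's exact test) and none of the 110 cuticle protein genes (0%, up to 3.298, adjusted p = 4.54e-09) had one. None of the 111 replication-dependent histone genes had one (adjusted p = 4.54e-09, Fisher's exact test), but these are repeated copies at which the pooled list held 0 regions, so this 0 may not be read as an absence of the protein. Transfer RNA genes had one in 13 of 290 cases (4.48%, odds ratio 0.269, 0.141 to 0.469, adjusted p = 1.81e-07, Fisher's exact test), with tRNA:Thr-TGT-2-3 (918), tRNA:Tyr-GTA-1-8 (442), tRNA:His-GTG-1-3 (212) and tRNA:Glu-TTC-1-5 (114) the highest. Their odds ratio was 0.420 in the list of replicate 2 alone and 0.453 at a promoter distance of 1000 bp, both past the threshold. Small nucleolar RNA genes had one in 16 of 269 cases (5.95%, odds ratio 0.364, 0.204 to 0.604, adjusted p = 4.42e-05, Fisher's exact test), led by snoRNA:U49:66Da (205, without a matched region in replicate 2), snoRNA:Or-CD11a (178) and the pair snoRNA:Or-aca5 and snoRNA:Psi28S-2949 at 1 peak (173). With a promoter distance of 1000 bp the small nucleolar RNA genes did not differ, with an odds ratio of 0.907, and with 250 bp it was 0.179.

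The developmental lists did not pass the threshold. Of 27 segmentation genes, 4 had a promoter peak, ptc with 1727 and nkd with 119.8 as the highest, and of 8 Hox genes only Scr (82.5) had one. The dorsoventral list had 1 of 15, tin (173), the early zygotic list 1 of 12, Sxl (83.5), and the E(spl) complex of Notch targets 4 of 11, with E(spl)m3-HLH (256.4) and E(spl)m2-BFM (218). Counts were 7 of 20 for heat shock genes, with Hsp27 (462) and Hsc70-5 (186), 5 of 17 for zinc finger genes with a ZAD domain, with pad (119.4) and M1BP (103), and 9 of 33 for cell cycle genes, with Dp (153) and Cdk1 (118). They were 16 of 80 for oxidative phosphorylation, with ND-ASHI (272) and ND-24 (216), 6 of 48 for the proteasome, with Rpn5 (183) and Rpn3 (149), and 2 of 20 for the piRNA pathway, vas (91.8) and piwi (74.0). Neuronal genes had 1 of 18, elav (378), muscle genes 2 of 17, sls (105) and Tm1 (88.7), and small nuclear RNA genes 4 of 32, with snRNA:U2:34ABb (129.9) and snRNA:7SKa (82.4). The testis (0 of 21, up to 16.1%), yolk and chorion (0 of 12, up to 26.5%) and dosage compensation (0 of 6, up to 45.9%) lists had none, with adjusted p values of 0.0947, 0.274 and 0.735 (Fisher's exact test). In the upper 1997 peaks the E(spl) complex (4 of 11, odds ratio 5.04, adjusted p = 0.0486) and heat shock genes (6 of 20, odds ratio 3.78, adjusted p = 0.0333) passed, and at a promoter distance of 1000 bp the testis list did (0 of 21, adjusted p = 0.0389, Fisher's exact test).

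**Figure D4:**
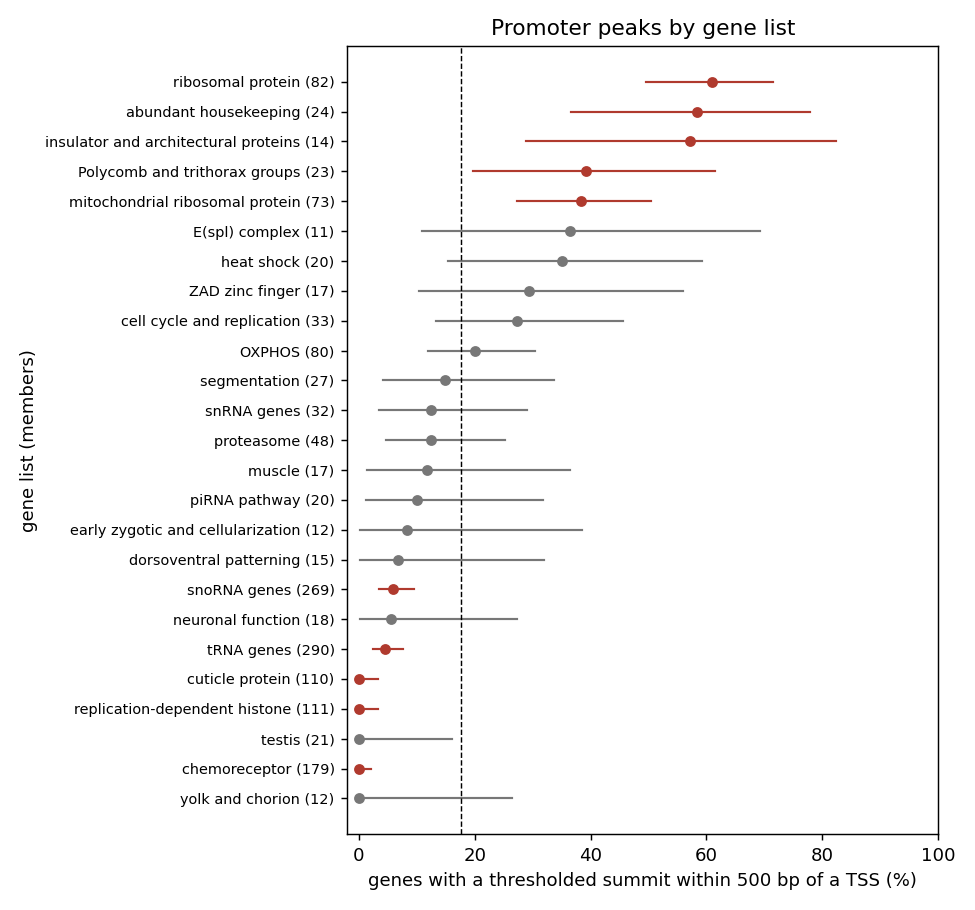
Share of the members of each gene list with a promoter peak (x axis, percent; points, with exact 95% intervals as lines), lists of 10 or more members with their size on the y axis. Red marks an adjusted p under 0.05, and the dashed line is the 17.7% of all protein-coding genes; ribosomal protein genes reach 61.0%.

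The chromosomes were compared to see whether binding differed between X and the autosomes. On X, 341 of 2196 protein-coding genes had a promoter peak (15.5%, 14.04 to 17.1), against 2120 of 11669 (18.2%, 17.5 to 18.9) on 2L, 2R, 3L and 3R. The odds ratio was 0.828 (0.729 to 0.939, Fisher's exact p = 0.00284, two-sided). Single autosome arms also differed, from 16.5% on 2R (15.1 to 17.9) to 19.4% on 3R (18.1 to 20.8), and the intervals of X and 2R overlapped. The contrast may therefore not be particular to X. The number of X copies in embryos of both sexes was not accounted for, so the odds ratio cannot be read as weaker binding on X. The large arms held 28.2 peaks per Mb on 2R to 31.5 on 2L. Chromosome 4, the small and largely heterochromatic autosome, held 15 peaks, 11.1 per Mb, although its 540 regions in the pooled list came to 401 per Mb, against 222 per Mb on the other arms. Of its regions 2.78% entered the thresholded set, against 13.5% elsewhere (odds ratio 0.183, 0.102 to 0.305, Fisher's exact p = 1.99e-17). By genes the deficit was smaller: 7 of its 80 protein-coding genes had a promoter peak (8.75%), against 17.7% elsewhere (odds ratio 0.444, 0.172 to 0.964, Fisher's exact p = 0.0384). The tests of chromosome 4 were added after its count of peaks was seen.

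The sequence at the summits was examined for sites of known factors. Summits were poor in G and C: the mean G+C content in the central 51 bp was 32.6%, against 43.1% at 1000 bp upstream. The replication-related element TATCGATA (DRE), the site of Dref, lay in 55 of the 3995 summit windows and 12 flank windows (4.58-fold, adjusted p = 6.85e-07, exact McNemar test). TATA sites were in 351 against 153 windows (adjusted p = 2.08e-18), paired BEAF-32 sites in 32 against 14 (adjusted p = 0.0284), Motif 1 in 23 against 9 (adjusted p = 0.0401), and runs of 8 A in 317 against 217 (adjusted p = 4.86e-05, exact McNemar test). Less frequent at summits were CA repeats, in 34 against 133 windows (adjusted p = 3.16e-14), GAGAGAG in 42 against 92 (adjusted p = 7.48e-05), the E-box CAGCTG in 123 against 192 (adjusted p = 0.000309), the Dorsal site in 29 against 55 (adjusted p = 0.0173) and CT repeats in 25 against 47 (adjusted p = 0.0284, exact McNemar test). The calls for Motif 1, the Dorsal site and CT repeats were lost in either replicate's own list and with the flank window that was not drawn. Paired BEAF-32 sites and runs of A lost theirs in the upper 1997 peaks and in windows of 51 bp, and the E-box CAGCTG lost its own without replicate 2. Paired BEAF-32 sites were in 47 against 11 windows without replicate 2 and in 32 against 8 with the flank that was not drawn, and Motif 1 was in 13 against 1 in windows of 51 bp. Only DRE, TATA, CA repeats and GAGAGAG kept their calls in all settings with a flank as background. The other 10 motifs, among them Zelda (18 against 19) and the CTCF core (136 against 143), did not pass the threshold. These contrasts changed against windows elsewhere matched on G+C content and promoter status together, an alternative chosen after the data were seen. Since both were matched at once, the part of base composition cannot be told apart. DRE remained more frequent (55 against 23, adjusted p = 0.00252), and TATA did not (351 against 354, exact McNemar test). Paired BEAF-32 sites kept a similar ratio (32 against 15) without passing the threshold (adjusted p = 0.0745, exact McNemar test). CA repeats remained less frequent (34 against 74, adjusted p = 0.00149), and the CTCF core was more frequent (136 against 54, adjusted p = 3.13e-08, exact McNemar test). Runs of A turned to less frequent (317 against 387), and CAGCTG (123 against 112), GAGAGAG (42 against 39) and CT repeats (25 against 22) were no longer depleted. Motif 1 (23 against 17, adjusted p = 0.793, exact McNemar test) and the Dorsal site (29 against 30) were no longer past the threshold.

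**Figure D5:**
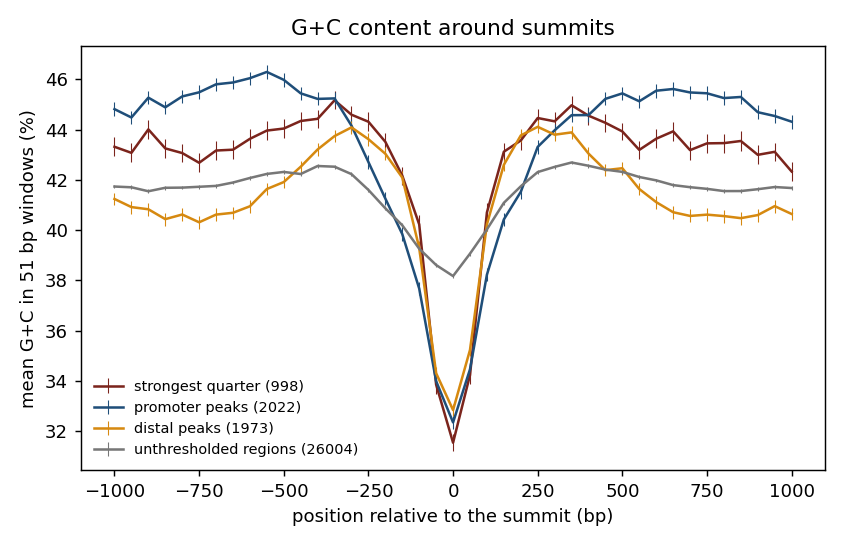
Mean G+C content in 51 bp windows (y axis, percent; error bars SEM over peaks) by position relative to the summit in bp (x axis) for the strongest 998 peaks, promoter peaks, distal peaks and the unthresholded regions of the pooled list. All 4 curves dip at the summit, to 31.5%, 32.4%, 32.8% and 38.2% in that order.

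Bound promoters were then set against promoters without any listed region, to separate sites of bound promoters from those that promoters share. DRE sites were in 49 of 2022 bound windows and 100 of 6960 unbound ones (2.42% against 1.44%, odds ratio 1.70, 1.18 to 2.43, adjusted p = 0.0219, Fisher's exact test). TATA sites (9.20% against 7.24%, odds ratio 1.30, adjusted p = 0.0219) and runs of A (7.42% against 5.07%, odds ratio 1.4997, adjusted p = 0.00101) were also more frequent, and the Initiator was less frequent (8.61% against 11.6%, odds ratio 0.715, adjusted p = 0.00101, Fisher's exact test). The other 16 motifs did not pass, but paired BEAF-32 sites did without replicate 2 (40 of 2115 against 54 of 6947, odds ratio 2.46, adjusted p = 0.000372, Fisher's exact test) and in the widest windows (odds ratio 1.72). Ohler 6 also passed as more frequent in the widest windows (odds ratio 1.59). In the other direction, CAGCTG passed as less frequent in the upper 1997 peaks (odds ratio 0.494), and CA repeats did so in windows of 51 bp (0.219). Bound promoter windows had a lower G+C content, 32.9% ± 9.42 (SD over windows), than unbound ones at 40.2% ± 10.4. The windows were not matched on it, so the calls for TATA sites, runs of A and the Initiator may follow base composition. The DRE call was lost in the upper 1997 peaks (odds ratio 1.59, adjusted p = 0.253, Fisher's exact test) and in windows of 51 bp (1.79), with similar odds ratios, and held without replicate 1 (2.13), without replicate 2 (1.67) and in the widest windows (2.16). In windows of 51 bp the calls for runs of A and the Initiator were lost as well, and the TATA call was lost in the widest windows tried.

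The search for 8-mers without a given motif asked which sequences marked the summits. On 2L and 2R, 139 of 32151 8-mers were more frequent at summits than in flanks, and 125 of them were so again on 3L, 3R, 4 and X, 89 of these made of A and T alone. The leading 8-mer was AAAATTAA, in 81 against 15 windows on 2L and 2R (adjusted p = 1.67e-08, exact binomial test) and in 148 against 61 on the held-out chromosomes (adjusted p = 3.59e-09). Against windows matched on G+C content and promoter status, the count fell to 1, ACCCTCGC, found in 21 against 0 windows (adjusted p = 0.0298) and again in 30 against 1 held-out windows (adjusted p = 2.98e-08, exact binomial test).

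The builds were compared by counts alone. The thresholded set held 3982 peaks in dm3 and 3995 in dm6, 99.7%, with median signals of 98.0 and 98.2. Chromosome 4 held 15 in both. The unthresholded lists differed more in size. The pooled list held 25074 regions in dm3 and 30000 in dm6, and that of replicate 2 held 28105 and 30000. That of replicate 1 held 30000 in both builds.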

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

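The test of the surplus of regions around CG18476 and that of a GC-rich 8-mer were chosen only after the results were seen. The 8-mer was first compared between the strongest and weakest 635 held-out peaks, which left it open (16 against 6, odds ratio 2.71, 0.998 to 8.51, Fisher's exact p = 0.0505), and the promoter against distal comparison that decided it was chosen after that. Regions on heterochromatin or unplaced scaffolds of dm3, which no comparison above used, numbered 49 in the pooled list, 65 in the list of replicate 1 and 76 in that of replicate 2. These counts lie above 3, the fixed bound for a count of 0, but no expected number was available, so this is not a test. None of these regions was in the dm3 thresholded set, and no explanation was tested. In dm6, the build analysed, the pooled list and that of replicate 1 held 1 region each off the 6 arms, on Y, and that of replicate 2 held 0. Whether the dm3 regions lie within the dm6 arms was not examined, since no coordinates were converted.

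Thresholded peaks lay at promoters 3.73-fold more often than random positions, for which a technical explanation is recovery of chromatin at highly expressed promoters whatever the tagged protein. Ribosomal protein and abundant housekeeping genes together had a promoter peak 7.13 times as often in odds as other genes (63 of 105, 95% interval 4.74 to 10.8, Fisher's exact p = 3.24e-22), as that explanation needs. Oxidative phosphorylation genes (16 of 80, odds ratio 1.16, 0.627 to 2.04) and proteasome genes (6 of 48, odds ratio 0.664, 0.2303 to 1.57) had no such excess (Fisher's exact test), and as expression was not measured here the explanation stays open. The leading A- and T-rich 8-mer gave no decision, with an odds ratio of 1.13 (0.679 to 1.87, Fisher's exact p = 0.716) between the strongest and weakest 635 held-out peaks, and the GC-rich 8-mer ACCCTCGC, if read by the protein or a partner, could not account for the promoter preference, since it lay in 9 of 2022 promoter peaks and 42 of 1973 distal ones (odds ratio 0.206, 0.0878 to 0.430, Fisher's exact p = 1.43e-06). A precipitation from untagged embryos was not analysed here, and beyond these sequences no biological explanation was tested.

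Chromosome 4 held 11.1 thresholded peaks per Mb against 30.0 on the other arms. Fewer copies of the 8-mer that led against flanks, AAAATTAA, could not explain this: it occurred 481 times per Mb on chromosome 4 and 270.2 times elsewhere. Peaks per copy were 0.208 times those of the other arms (0.117 to 0.344, exact Poisson interval). AAAATTAA was not kept against windows matched on G+C content and promoter status, however. Copies of ACCCTCGC, which was kept, and of the known motifs were not counted by arm, so a shortage of those on chromosome 4 is not excluded. The state of chromatin on that chromosome was not tested. Other arms also had stretches without thresholded peaks. On 3L the last such peak ended at 22879107, while regions of the pooled list ran to 28013583. On 2L these positions were 21867679 and 23369657, and on 2R, 3R and X they lay closer together. A lack of thresholded peaks may thus not be particular to chromosome 4.

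Around CG18476, 8 thresholded peaks lay within 20 kb of the gene, more than around 98.5% of protein-coding genes. A transgene copy of the locus may raise the background there. The pooled list held 20 regions in that span, the thresholded ones included, against a median of 12, more than around 85.5% of genes and short of the 95% set as the bound, and the 12 that were not thresholded, against a median of 10, were more than around 59.2%. The first calculation took regions per length in place of the number that the prediction named, and gave 90.6%. Since an extra copy could itself lift regions over the threshold, and the size of the insert and the control reads were not analysed here, the explanation stays open.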

How the results depend on the processing

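Results chosen after the data were seen were those with G+C-matched windows, the undrawn flank, the pooled-list background for X, the pooled-list and inner-arm comparisons of the promoter share, and the lists without peaks near tRNA genes. The promoter share, the X odds ratio and the promoter signal difference kept their direction and side of the threshold under every alternative run.

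Matched shares in replicate 1, replicate 2 and both were 86.2%, 89.4% and 76.5% for an overlap of 1 bp, 81.1%, 85.5% and 69.1% for summits within 100 bp, 87.2%, 90.4% and 85.5% for lists of 7990, and 77.9%, 83.4% and 76.6% for the upper 1997 peaks. Lists with more promoter peaks numbered 2 instead of 5 against genes in the pooled list. More and less frequent motifs at summits, 5 and 5 in the main test, numbered 2 and 3 in the upper 1997 peaks, 3 and 3 with windows of 51 bp, and 2 and 2 with G+C-matched windows. Without replicate 1 or 2, more frequent motifs numbered 4 to 5 and less frequent ones 3 to 3. At bound promoters, 2 motifs were less frequent in the upper 1997 peaks, and 1 was more frequent with windows of 51 bp. Kept 8-mers numbered 22 in the upper 1997 peaks, 235 with discovery and test chromosomes swapped and 1 with G+C-matched windows, 87 to 94 without a replicate, and 99 with the undrawn flank, which was added because the count had been seen to differ between draws of the flank side. The causes of these changes were not tested. The upper set holds fewer peaks, and the matched windows equal G+C content and promoter status at once, so neither can be credited alone.

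Reversals in the difference of windows with a site were seen with G+C-matched windows for the E-box CAGCTG (11), GAGA (3), TATA (-3), CT repeats (3), runs of A (-70), the CTCF core (82) and Zelda (10), and without replicate 1 or 2 for the CTCF core (-32 to 7) and Zelda (-8 to 2). Among the other 8 motifs, none past the threshold in the main test, 3 turned with G+C-matched windows, 2 in the upper 1997 peaks and 1 each without replicate 1 and with the undrawn flank, and calls were gained by Ohler 6 and ETS without replicate 2 and in the widest windows, by Ohler 6 and CACGTG with flanks at 500 bp, and by CACGTG with the undrawn flank. Odds ratios of lists that did not pass turned for segmentation (1.10 in the upper 1997 peaks, 1.22 against genes in the pooled list), dorsoventral patterning (1.42 at 1000 bp), the E(spl) complex (0 at 250 bp), cell cycle (0.969 against genes in the pooled list) and oxidative phosphorylation (0.978 in the upper 1997 peaks, 0.836 against genes in the pooled list). Without replicate 1 or 2 they turned for Hox (0.699 to 1.46), muscle (0.583 to 1.05) and oxidative phosphorylation (0.949 to 1.18). Over the lists, the motifs called or named at summits and those called at bound promoters, 244 other values stayed on their side, 38 were no longer past the threshold and 3, all of lists, came past it. No paired analysis was possible because the series holds 1 group. Depth is unknown from the lists, so its limit on weak peaks could not be measured.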

Other observations

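Divergent promoters were bound more often than others. Of 5052 protein-coding genes with an oppositely oriented TSS within 1000 bp upstream, 1626 (32.2%) had a promoter peak, against 842 of 8893 other genes (9.47%, odds ratio 4.54, 4.13 to 4.98, Fisher's exact p = 5.87e-241). A peak between a divergent pair counts for both genes, which inflates this contrast, and that part was not removed. The comparison and those below were chosen after the data were seen.

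A GC-rich core, GCGAGGG, shared by several 8-mers that were more frequent at all summits than in G+C-matched windows, lay in 108 of 3995 summit windows (2.70%, 95% interval 2.22 to 3.25) and in 14 matched windows. It lay in 4.36% of distal and 1.09% of promoter peaks (odds ratio 0.241, Fisher's exact p = 6.70e-11) and in 42 of the strongest 998 and 22 of the weakest 999 peaks (odds ratio 1.95, 1.13 to 3.46, Fisher's exact p = 0.0111). The core was selected on these same peaks and was the only one tried. In the cleaner comparison, of ACCCTCGC in held-out peaks, 16 of the strongest 635 and 6 of the weakest 635 had it (odds ratio 2.71, 0.998 to 8.51, Fisher's exact p = 0.0505), which missed the threshold. Of the 25 strongest peaks, 5 held the core within 50 bp of the summit, those at RhoGEF4, ptc, Pgant5, jumu and spin. At the RhoGEF4 peak it began at 3L:7323443.

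Over all peaks, 36 8-mers were more frequent at summits than in the matched windows. They included CACTGTGC in 46 against 3 windows (adjusted p = 7.62e-07, exact binomial test), CACAGTGG in 53 against 7 (adjusted p = 6.28e-06), CACTGAGA in 48 against 7 (adjusted p = 7.15e-05) and AGGTGGCG in 28 against 2 (adjusted p = 0.00167). Only ACCCTCGC was past the threshold on 2L and 2R alone, so the others have no held-out test.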
